A study of Mus musculus with 12 samples.

How the data were processed

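Bulk RNA-seq was measured in 12 libraries of tumour tissue labelled MB from mice of both sexes at end point. Total RNA was extracted with a Trizol-type protocol and sequenced at BGI on the BGISEQ-500 platform, per the labels. The labels put 3 libraries in each of 4 groups by genotype and sex, numbered 1 to 12 without repeats: SG male (1 to 3), SG female (4 to 6), YSGr male (7 to 9) and YSGr female (10 to 12). They give no batch, litter or animal number and nothing pairs libraries. Because nothing states that the libraries came from separate animals, p-values measure the spread between these samples, which may be technical in part.

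The authors deposited 1 table of log2 CPM (log2 of counts scaled to a common library size) with 15672 genes and the 12 libraries as columns. Per the submitters' processing notes, the authors named Trimmomatic 0.33, RSEM 1.2.12, Bowtie2, Picard 1.95 and edgeR 3.30.3 and the genome build mm10. The step that each tool served, the gene annotation, the use of strand in counting and the filter on low genes are not given in the sources used here. Turned back from log2, the deposited values of each library lay on steps of equal size. The lowest value was -2.24 log2 CPM in every library, the value that a prior count averaging 2 reads gives a gene with no reads. The step gave estimated reads per gene, which were whole within 0.02 reads for 92.0 to 93.0% of genes, so the values came from estimated counts. Estimated reads summed to 8854765 to 9478649 per library, 1 read was worth 0.100 to 0.111 CPM, and a floor of 3 reads in 1 library corresponds to 0.301 to 0.333 CPM. The deposited values use library sizes scaled by factors of 0.951 to 1.081. The 10 most abundant genes took 5.87 to 6.96% of the reads of a library. No pair of libraries held identical values (0 pairs). Pearson correlations across genes within a group were 0.971 to 0.991 in SG males, 0.991 in SG females, 0.959 to 0.984 in YSGr males and 0.969 to 0.982 in YSGr females.

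Of the gene names, 15580 (99.4%) matched the GENCODE M21 annotation, 15572 of them as protein coding, and 22 were bare numbers with no gene symbol. There were 79 genes at the lowest value in all libraries. Xist and Tsix, which are on the sex-linked list, were not analysed here. Coordinates are from GENCODE M21, which uses the mm10 build.

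Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on the log2 CPM values as deposited, without a further pseudocount. Fold changes are therefore on a scale that includes the prior count and understates the change of low genes. A gene entered with log2 CPM above 0 in at least 3 of the 12 libraries (14147 genes). One coefficient was fitted per group, all 12 libraries shared the estimate of the spread, eBayes used a mean-variance trend, and tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes are from this limma fit. The contrasts were YSGr against SG averaged over the sexes, in females and in males, the difference between the female and the male effect, and females against males within each genotype. The female and the male contrast share no libraries, and the averaged contrast uses those of both.

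Before the data were examined, 36 gene lists were fixed. The 18 lists of pathways and gene classes covered Yap1 and Hippo pathway genes, YAP targets, the Sonic hedgehog pathway, cell cycle, type I interferon and interferon gamma responses, MHC class I and class II, complement, chemokines and inflammatory cytokines, immune checkpoints, hypoxia and glycolysis, extracellular matrix, cholesterol synthesis, immediate early genes, mitochondrially encoded genes, ribosomal proteins and sex-linked genes. The 18 lists of cell type markers covered granule neuron progenitors, differentiating granule neurons, neural stem cells and astrocytes, the oligodendrocyte lineage, microglia, infiltrating macrophages and monocytes, neutrophils, dendritic cells, T cells, cytotoxic lymphocytes and NK cells, B and plasma cells, endothelial cells, pericytes with fibroblasts and meninges, ependyma with choroid plexus, erythroid cells, Purkinje cells and interneurons, neurons of forebrain and other regions, and skeletal muscle with skin. Some genes are on more than 1 list. The 32 lists with at least 5 tested members were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which tests whether a list's genes move, on balance, one way, were alternatives. Members past the threshold were counted over all genes tested and adjusted over the list alone.

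The rule for named genes was also fixed before the data were examined. It takes Yap1 and 16 further genes in any case, then per contrast the 10 genes with the largest fold change in each direction among those past the threshold, with mean log2 CPM above 1 and no overlap between the groups (predicted genes left out), then up to 4 members per list by smallest p, and the sex-linked genes. The condition of no overlap was not applied to the difference between the sexes. Full values are given for at most 10 of the leading genes of a contrast. Ratios of CPM use the estimated reads without the prior count. Where a group had 0 reads the ratio is a bound against 3 reads over the group, and with 1 to 3 reads it has a 95% Clopper-Pearson interval, taken on the share of the reads that fell in the higher group. These intervals and bounds cover counting error only.

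Reads of near-identical or overlapping genes may have been split by the authors' counting, and values of such genes are uncertain. Hmga1 and Hmga1b, Pagr1a and Pagr1b, and members of the tubulin, enolase, Duxbl, Ifi, Oas, Gbp, Ifit and H2 families have close copies. In the annotation Mndal overlaps Ifi203, Irgm2 overlaps Igtp, mt-Atp8 overlaps mt-Atp6 and Igf2 overlaps a predicted gene on the same strand. Cxcl10 lies within Art3, Gpr34 within Cask, and Shisa3, Timp1, Alx4, Ccnd1, Junb, Rps14 and Crim1 overlap a gene on the opposite strand.

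The test was run on simulated data first, with 100 genes changed at each of 2 fold sizes among 14147 genes. Changes of 2-fold were called for 83% of genes in the averaged contrast, 60% in females and 54% in males, and changes of 4-fold for 98%, 95% and 95%. In those runs 7, 5 and 12 unchanged genes were called. The simulation drew independent normal noise for each gene at its measured spread, with the same change in both sexes. It held no shift shared by the genes of a library, so these shares may not hold for the real data.

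Alternatives chosen before the data were examined were no filter or a stricter one (log2 CPM above 1 in at least 6 libraries), log2(CPM + 1) and log2(CPM + 5), median centring, quantile normalization, no variance trend, a robust variance, library weights, fits on only the groups compared, genotype alone, genotype plus sex, and leaving out each library in turn. After the data were seen, limma's voom on the recovered reads, a correction of each library for exon length and GC content, and leaving out libraries 2 and 8 together were added. Voom called 1552 genes in the averaged contrast, 388 in females, 1008 in males, 1 for the difference between the sexes, and 5 and 12 between the sexes of SG and YSGr. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.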

Results

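Gene expression was profiled in medulloblastoma tissue, a tumour of the cerebellum, from mice at end point. SG tumours carried a conditional allele of SMO-M2, an activated form of the Hedgehog signal transducer Smoothened, with Cre recombinase under the human GFAP promoter. YSGr tumours carried a floxed Yap1 allele in addition and are called rescued in the labels, which do not say what was rescued. Yap1 encodes a transcriptional coactivator that the Hippo pathway restrains. There were 12 libraries, 3 each of SG males, SG females, YSGr males and YSGr females, with 8854765 to 9478649 estimated reads per library. In a principal component analysis the first component held 38.3% of the variance, with YSGr male 8 farthest out at 74.5. The third held 12.3%, with SG male 2 apart at -57.0.

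Yap1 (chromosome 9, 7931999 to 8004596) was lower in all 6 YSGr libraries than in all 6 SG libraries. It had 174 to 253 estimated reads per SG library, 33, 29 and 14 in the YSGr males and 9, 12 and 7 in the YSGr females. Mean log2 CPM was 4.48 ± 0.18 (SD, n = 6) in SG and 0.83 ± 0.77 (SD, n = 6) in YSGr, a log2 fold change of -3.64 ± 0.20 (SE, adjusted p = 1.1e-06). By CPM Yap1 was 12.2-fold lower over both sexes, 23.8-fold lower in females (log2 fold change -4.32, SE 0.29, adjusted p = 9.9e-06) and 7.94-fold lower in males (-2.96, SE 0.29, adjusted p = 0.00027). The difference between these effects was -1.36 and did not pass the threshold (adjusted p = 0.43). Values are sums over the gene and do not show which exons the remaining reads came from.

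The first comparison asked how YSGr tumours differed from SG tumours with the sexes weighted equally. Lcn2, which encodes a siderophore-binding protein of neutrophil granules and reactive astrocytes, rose by 5.67 (log2 fold change, SE 0.48, adjusted p = 2.4e-05). Complement component C3 rose by 3.97 (SE 0.36, adjusted p = 4.2e-05), Cd74, the invariant chain of MHC class II, by 3.83 (SE 0.35, adjusted p = 4.8e-05), and Cxcl1, a chemokine that attracts neutrophils, by 3.55 (SE 0.24, adjusted p = 5.1e-06). The leading decreases included the RNA-binding protein gene Igf2bp1 at -4.23 (SE 0.35, adjusted p = 2.1e-05) and Pgf, placental growth factor, at -2.69 (SE 0.23, adjusted p = 3.0e-05). In total 1617 of 14147 genes passed the threshold, 871 higher and 746 lower in YSGr.

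The other leading increases were Mndal and Ifi203, neighbouring interferon-inducible genes that overlap and share reads, Tgm1, Shisa3, H2-Aa and Cxcl10, with log2 fold changes of 3.37 to 5.51. Other leading decreases included Pdlim3, Hmga1b, Tuba1c, Loxl1, Gpr50 and Eln, with -4.43 to -2.44. Loxl1 and Eln encode a lysyl oxidase-like enzyme and the elastin it crosslinks. Tuba1c and Hmga1b have near-identical copies and are uncertain. Spread within YSGr was wide for Pdlim3, at 0.82 to 6.20 log2 CPM. Mndal had 7 reads in YSGr male 8 and 252 to 741 in the other YSGr libraries, and Ifi203 19 and 121 to 352. Neither followed the type I interferon list within YSGr. The mean log2 CPM of that list was 2.03 in YSGr male 8. It was lowest, at 1.20, in YSGr female 12, which had the most reads of both genes. The reason was not tested.

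**Figure D1:**
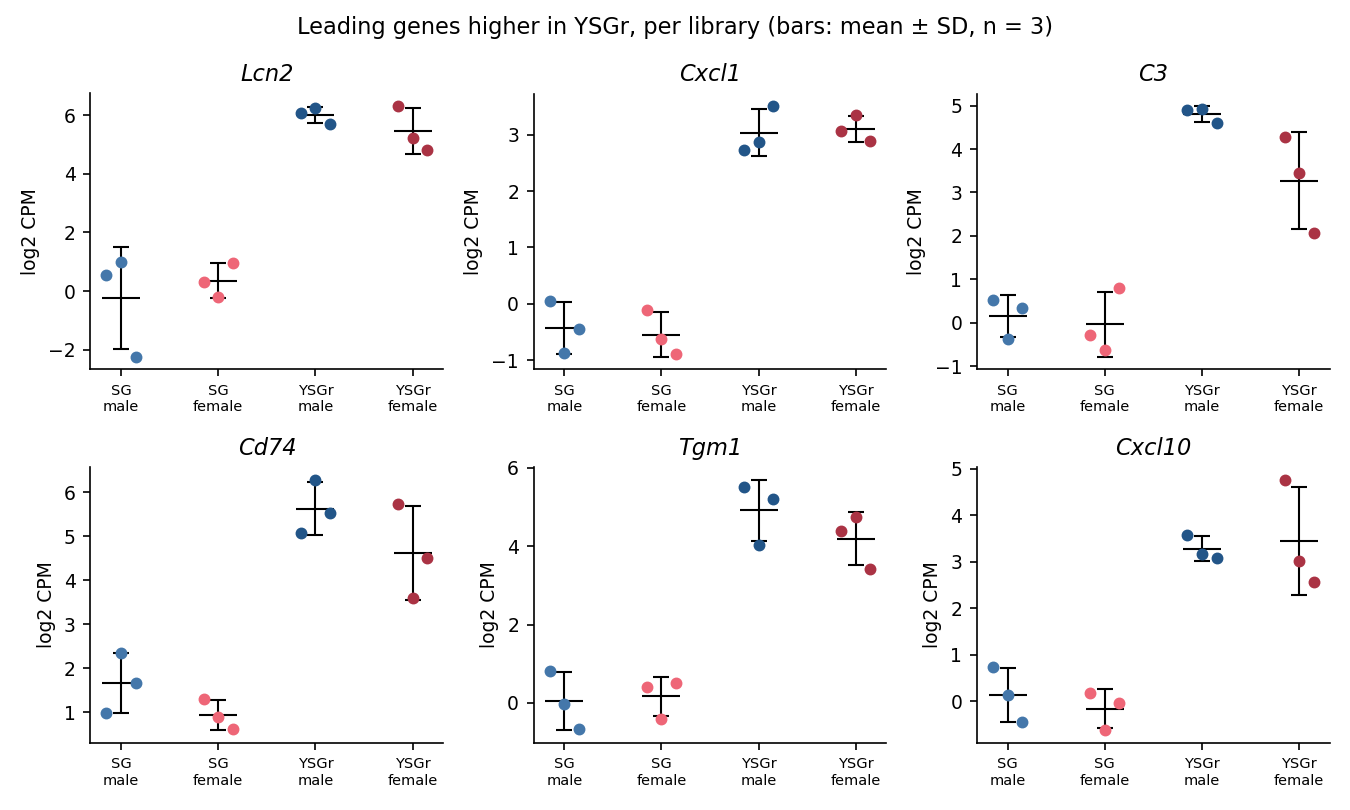
Log2 CPM of Lcn2, Cxcl1, C3, Cd74, Tgm1 and Cxcl10 in each library by group; points are libraries and bars the mean ± SD of 3. All 6 YSGr libraries lie above all 6 SG libraries for each gene.

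All 8 lists of interferon, antigen presentation, complement, chemokine, macrophage and neutrophil genes were higher in YSGr. Of the chemokines and inflammatory cytokines 10 of 20 rose and 0 fell (14 and 0 adjusted over the list alone, median 1.16), with Ccl2 at 2.57 and Il1b at 2.95, and the call held in both camera tests (adjusted p = 2.9e-11, and adjusted p = 0.020 with an estimated correlation). Infiltrating macrophage and monocyte markers also held in both (adjusted p = 9.7e-06, and adjusted p = 0.040 with an estimated correlation), with 7 of 16 risen, among them Gpnmb at 1.98, Lyz2 at 1.79 and Lgals3 at 2.48, and 1 fallen (10 and 1 adjusted over the list alone, median 0.85). Complement genes rose in 13 of 16 cases (14 adjusted over the list alone), among them C1ra at 2.24 and C4b at 1.26, with a median of 0.80 (camera adjusted p = 5.5e-11, but adjusted p = 0.065 with an estimated correlation). Neutrophil markers rose in 7 of 8 cases (7 adjusted over the list alone), with S100a9 at 3.08, Mmp9 at 2.64 and Cxcr2 at 2.62 and a median of 2.42 (camera adjusted p = 5.7e-08, but adjusted p = 0.065 with an estimated correlation).

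Among type I interferon response genes 12 of 25 rose (17 adjusted over the list alone, median 0.80), among them Oas1a at 2.27 and Irf7 at 1.70 (camera adjusted p = 5.0e-10, adjusted p = 0.19 with an estimated correlation). Interferon gamma response genes rose in 13 of 24 cases (16 adjusted over the list alone, median 0.91), with Gbp5 at 1.71 and Irgm2 at 1.03 (camera adjusted p = 6.6e-09, adjusted p = 0.13 with an estimated correlation). MHC class II genes, which present antigen on professional presenting cells, rose in 6 of 9 cases (6 adjusted over the list alone, median 1.83), including H2-Ab1 at 2.87 and H2-Eb1 at 3.16 (camera adjusted p = 2.3e-05, adjusted p = 0.24 with an estimated correlation). MHC class I genes rose in 5 of 12 cases (7 adjusted over the list alone, median 0.59), with B2m at 0.62 and H2-D1 at 0.55 (camera adjusted p = 0.00074, adjusted p = 0.26 with an estimated correlation).

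Cd274, which encodes the checkpoint ligand PD-L1, rose by 1.51 (SE 0.32, adjusted p = 0.0089), while the checkpoint list as a whole had 1 gene risen and 2 fallen of 12 (1 and 2 adjusted over the list alone, median 0.18, camera adjusted p = 0.22). Transcripts of the T cell genes Cd3e and Cd8a were near the detection limit. Cd3e had 2 estimated reads over the SG libraries and 5 over the YSGr libraries (ratio 2.46, 95% interval 0.40 to 25.9), and Cd8a had 3 and 11 (ratio 3.61, 95% interval 0.95 to 20.2), of which 7 were in YSGr male 8 (ratio 1.57 without it, 95% interval 0.27 to 10.7). Without SG male 2 or SG male 3 the Cd3e ratio rested on 1 SG read, at 4.14 and 4.10. Without YSGr male 7 or YSGr female 10, 11 or 12, which had 0 or 1 Cd8a read, the Cd8a ratio was 3.94 to 4.38. Those intervals lay above 1 (lowest limit 1.02), and in the other leave-outs the Cd8a interval held 1. Neither gene was tested, and with all 12 libraries no difference was detectable at this depth. Of T cell genes 4 passed the filter and 0 changed (0 adjusted over the list alone, median 0.42). The single cytotoxic and NK list gene measured was Eomes, also a marker of cerebellar unipolar brush cells, at 0.38 (adjusted p = 0.63). Both B and plasma cell genes measured, with Xbp1 at 0.38, were not past the threshold. Dendritic cell markers went both ways, with 3 of 8 risen and 1 fallen (5 and 1 adjusted over the list alone, median 0.54), Bst2 at 0.79 and Fscn1 at -0.93 (camera adjusted p = 0.043, adjusted p = 0.26 with an estimated correlation). That call ended without SG male 2 (adjusted p = 0.065), SG male 3 (0.074), SG female 6 (0.053), YSGr male 7 (0.061), YSGr male 8 (0.056) or YSGr female 10 (0.054). Microglia markers were not higher, with 0 of 13 risen and 1, Gpr34 at -0.63, fallen (0 and 2 adjusted over the list alone, median 0.02 and mean below 0, camera adjusted p = 0.88).

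Hedgehog pathway genes were lower in YSGr. Of 18 measured, 0 rose and 8 fell (1 and 12 adjusted over the list alone, median -0.47, camera adjusted p = 7.9e-05, adjusted p = 0.26 with an estimated correlation). Gli1, the transcription factor that reads out pathway activity, had a log2 fold change of -0.82 (SE 0.13, adjusted p = 0.0018), Gli3 of -1.65 (SE 0.31, adjusted p = 0.0052), Ccnd1, which encodes cyclin D1, of -0.60 (SE 0.10, adjusted p = 0.0032), and Smo of -0.41 (SE 0.08, adjusted p = 0.0046). Ptch1 at -0.57 (adjusted p = 0.11) and Mycn at -0.16 (adjusted p = 0.55) did not pass. For Ptch1 SG male 2 lay apart at 8.30 log2 CPM. The other SG libraries, at 9.48 to 9.95, were above all YSGr libraries, at 8.48 to 9.20. Of granule neuron progenitor markers 0 rose and 4 of 16 fell, including Atoh1 at -0.59, Hes6 at -0.87 and Mfap4 at -1.62 (0 and 5 adjusted over the list alone, median -0.07, camera adjusted p = 0.12, but adjusted p = 0.033 without YSGr male 9). Cell cycle genes had a median of -0.32 with 2 of 30 fallen (1 adjusted over the list alone) and Mki67 at -0.35 (adjusted p = 0.21). The cell cycle call (camera adjusted p = 1.5e-05, adjusted p = 0.41 with an estimated correlation) had a median of -0.21 without YSGr female 11.

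**Figure D2:**
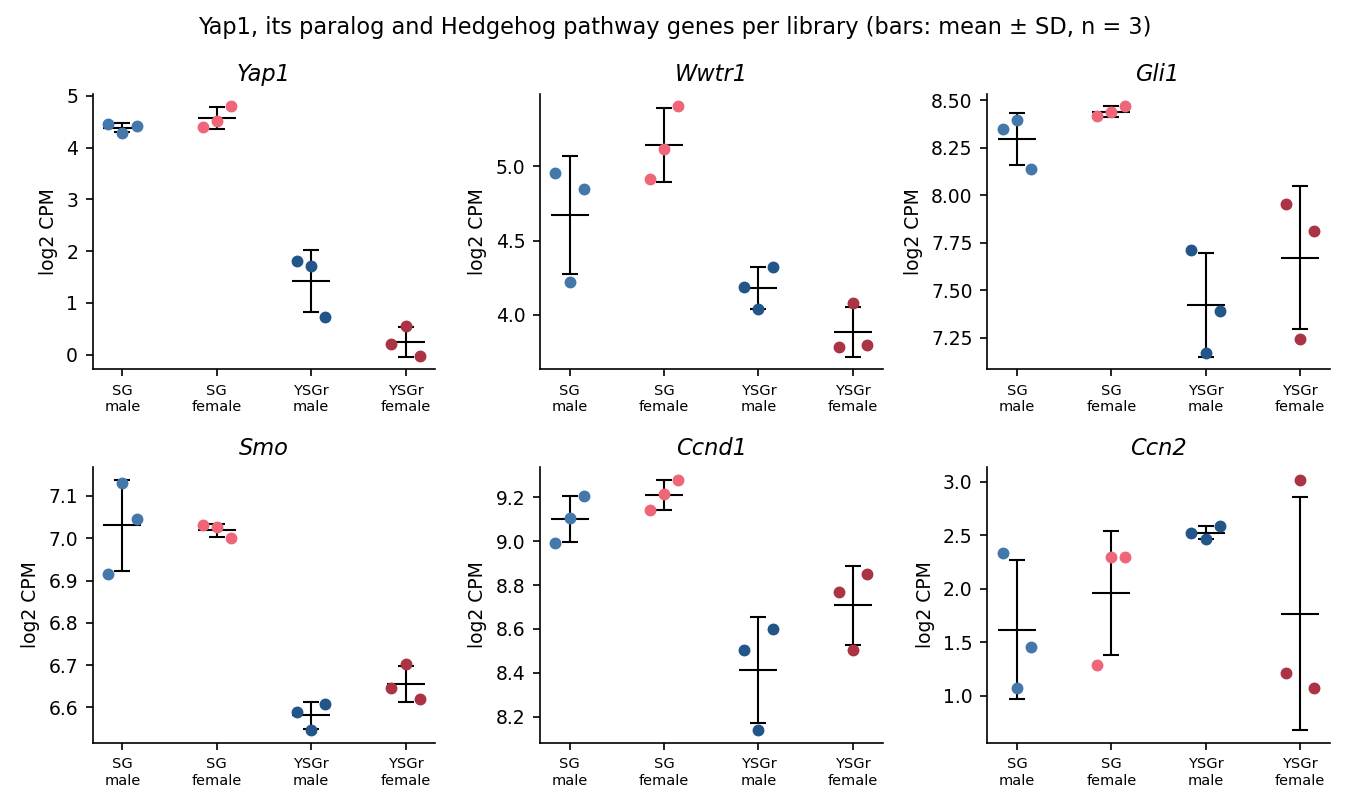
Log2 CPM of Yap1, Wwtr1, Gli1, Smo, Ccnd1 and Ccn2 in each library by group; points are libraries and bars the mean ± SD of 3. YSGr means lie below SG means in both sexes for each of these genes but Ccn2, at 0.36 (adjusted p = 0.53), and the libraries of the genotypes overlap for Wwtr1 and Ccn2.

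Hippo pathway genes included 6 of 23 that fell and 0 that rose (7 and 0 adjusted over the list alone, median -0.23, camera adjusted p = 0.00011, adjusted p = 0.26 with an estimated correlation). Besides Yap1 these included its paralog Wwtr1, which encodes TAZ, at -0.88 (SE 0.15, adjusted p = 0.0025). Tead2, a DNA-binding partner of both, was at -0.75 (SE 0.12, adjusted p = 0.0016). The fall of Yap1 itself follows from the design, and the list was not tested without Yap1 in any comparison. The median was -0.36 without SG male 2. YAP target genes as a list were not past the threshold in the average (median -0.17, camera adjusted p = 0.51), where the sexes had opposite signs. The list was lower in females (median -0.39, camera adjusted p = 0.0057, adjusted p = 0.18 with an estimated correlation), a call that ended without YSGr female 12 (median -0.22, adjusted p = 0.064), and not past the threshold in males (median 0.16, camera adjusted p = 0.40). Averaged over the sexes 1 of 21 rose, Myof, and 1 fell, Nt5e (2 and 4 adjusted over the list alone). Widely used targets did not pass, with Ccn1 at -1.10 (adjusted p = 0.061), Ccn2 at 0.36 (adjusted p = 0.53) and Amotl2 at -0.25 (adjusted p = 0.30).

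Neural stem cell and astrocyte markers fell in 6 of 20 cases and rose in 1, Gfap (8 and 1 adjusted over the list alone, median -0.38, camera adjusted p = 0.00046, adjusted p = 0.13 with an estimated correlation). Sox2 fell by 0.69 (SE 0.13, adjusted p = 0.0044), and the Notch effectors Hes5 and Hes1 were at -1.69 and -1.37, while Gfap, an astrocyte filament protein, rose by 0.98 (SE 0.22, adjusted p = 0.014). Differentiating granule neuron markers rose in 6 of 20 cases and fell in 0, with Snap25 at 1.16 and Car10 at 0.75 (9 and 0 adjusted over the list alone, median 0.58, camera adjusted p = 0.00050, adjusted p = 0.31 with an estimated correlation). The median was 0.37 without YSGr female 11. Forebrain and other neurons had 2 of 7 risen and 1 fallen (4 and 1 adjusted over the list alone, median 0.60, camera adjusted p = 0.073, but adjusted p = 0.041 without YSGr male 8), with Tbr1, also expressed in cerebellar nuclei, at 1.42. Purkinje cell and interneuron markers had 0 risen and 1, Foxp2, fallen of 15 (0 and 1 adjusted over the list alone, median 0.34, camera adjusted p = 0.29).

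Vessel and matrix lists were lower when averaged over the sexes, with calls in females and, with all 12 libraries, none in males. Without YSGr male 8 the pericyte list also passed in males (camera adjusted p = 0.022). Extracellular matrix genes fell in 7 of 20 cases and rose in 3 (11 and 4 adjusted over the list alone, median -0.58, camera adjusted p = 0.0026, adjusted p = 0.26 with an estimated correlation). The basement membrane collagens Col4a1 and Col4a2 were at -1.72 (SE 0.11, adjusted p = 1.9e-06) and -1.47 (SE 0.11, adjusted p = 1.5e-05), and the fibrillar Col3a1 at -1.62 (SE 0.20, adjusted p = 0.00042), while Timp1, an inhibitor of matrix metalloproteinases, rose by 2.43 (SE 0.28, adjusted p = 0.00024). Pericyte, fibroblast and meningeal markers fell in 5 of 17 cases and rose in 1 (5 and 1 adjusted over the list alone, median -0.46, camera adjusted p = 0.0010, adjusted p = 0.26 with an estimated correlation), among them Igf2 at -1.99 and Pdgfrb at -1.09. Endothelial markers fell in 5 of 14 cases and rose in 1 (6 and 1 adjusted over the list alone, median -0.34), with the VEGF receptor gene Kdr at -1.55 and Cldn5, a blood-brain barrier claudin, at -1.11 (camera adjusted p = 0.020, adjusted p = 0.41 with an estimated correlation). The endothelial call ended without YSGr male 7 (adjusted p = 0.076) and its median was -0.52 without YSGr male 8.

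Cholesterol synthesis genes had 0 risen and 3 of 18 fallen, with Mvk at -0.65 and Srebf2 at -0.44 (0 and 6 adjusted over the list alone, median -0.29, camera adjusted p = 0.00058, adjusted p = 0.31 with an estimated correlation). Immediate early genes had 3 of 15 risen and 1 fallen (8 and 2 adjusted over the list alone, median 0.50, camera adjusted p = 0.0092, adjusted p = 0.24 with an estimated correlation), with Junb at 1.14 and Ier2 at -0.79. Ribosomal protein genes had a median of -0.39 with 0 of 30 risen and 1, Rplp0 at -0.78, fallen (0 and 1 adjusted over the list alone, camera adjusted p = 9.7e-06, adjusted p = 0.49 with an estimated correlation). Their median was -0.24 without SG male 2, which had the highest mean level of these genes, 9.86 log2 CPM against 8.85 to 9.03 in the other SG libraries.

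The remaining lists did not pass camera with all 12 libraries. Hypoxia and glycolysis genes had 2 risen and 1 fallen of 17 (2 and 1 adjusted over the list alone, median 0.03, adjusted p = 0.26), mitochondrially encoded genes 1 risen, mt-Atp8, and 0 fallen of 13 (1 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.052) and sex-linked genes 0 changed of 8 (0 adjusted over the list alone, median -0.04, adjusted p = 0.82). Oligodendrocyte lineage markers had 0 risen and 3 fallen of 18, including Olig1 at -0.68 and Olig2 at -0.67 (0 and 3 adjusted over the list alone, median 0.15 with camera pointing down, adjusted p = 0.71). Ependymal and choroid plexus markers had 1 of 12 fallen, Clic6 at -1.36 (median 0.14 with mean below 0, adjusted p = 0.82). Erythroid genes had 0 of 7 changed (0 adjusted over the list alone, median -0.80, adjusted p = 0.19). The mitochondrially encoded list passed in 6 of 12 leave-outs, without SG male 1 (adjusted p = 0.043), SG male 3 (0.049), SG female 5 (0.026), SG female 6 (0.032), YSGr male 9 (0.012) or YSGr female 10 (0.030). The erythroid list passed without SG male 1 (adjusted p = 0.025, median -1.23). The 3 muscle and skin genes measured included 1 that fell, Acta1 (adjusted p = 0.043).

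In this averaged comparison 4044 genes had an unadjusted p under 0.05, against 707 expected by chance. Of the 106 named genes called, 89 kept the call in all 12 leave-outs, the 20 leading genes among them. The count of genes was 919 without SG female 5, 903 without SG female 6, 1030 without YSGr female 10 and 4986 with library weights.

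In females, the question was which of these differences arose between YSGr and SG tumours of that sex alone. There 426 genes passed the threshold, 162 higher and 264 lower (2130 at an unadjusted p under 0.05). Cxcl1 rose by 3.65 (SE 0.34, adjusted p = 0.00021), Lcn2 by 5.10 (SE 0.67, adjusted p = 0.0018) and Cd74 by 3.69 (SE 0.49, adjusted p = 0.0020). The other leading increases were Mndal, Ifi203, Tgm1, H2-Aa, Shisa3, Cxcl10 and C3, at 3.30 to 6.60. Igf2bp1 fell to 2 estimated reads over the 3 YSGr females against 284 in the SG females, a CPM ratio of 142 (95% interval 38.9 to 1178), and Hmga1b, a near-identical copy of Hmga1, fell by 5.14 (SE 0.21, adjusted p = 3.7e-08). Other leading decreases included Yap1, Robo3, Grb10, Fmod, Adamts12, Pgf and Col5a2, at -4.32 to -2.67. Fmod, Adamts12 and Col5a2 act in the extracellular matrix.

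Matrix and vessel lists were lower in females. Extracellular matrix genes fell in 7 of 20 cases and rose in 1 (11 and 3 adjusted over the list alone, median -0.91, camera adjusted p = 9.3e-08, adjusted p = 0.088 with an estimated correlation), with Col4a1 at -1.80 and Col3a1 at -2.09. Pericyte, fibroblast and meningeal markers fell in 5 of 17 cases (9, with 1 risen, adjusted over the list alone, median -0.73, camera adjusted p = 1.9e-07, adjusted p = 0.11 with an estimated correlation), with Pdgfrb at -1.64. Endothelial markers fell in 2 of 14 cases (6 adjusted over the list alone, median -0.70, camera adjusted p = 4.2e-06, adjusted p = 0.15 with an estimated correlation), with Kdr at -1.60. Among immune lists, chemokines and cytokines had 5 of 20 risen (11 adjusted over the list alone, median 1.17) and held in both tests (camera adjusted p = 1.8e-09, adjusted p = 0.035 with an estimated correlation). Complement, with 3 of 16 risen (8 adjusted over the list alone, median 0.62), neutrophil, with 2 of 8 risen (4 adjusted over the list alone, median 1.69), and macrophage markers, with 4 of 16 risen and 1 fallen (6 and 1 adjusted over the list alone, median 0.66), passed camera (adjusted p = 2.1e-08, 2.2e-06 and 0.00034), and each had adjusted p = 0.088 with an estimated correlation. The macrophage median was 0.40 without YSGr female 11. Interferon and MHC lists passed camera in females with few members past the threshold. Type I interferon response genes had 1 of 25 risen (3 adjusted over the list alone, median 0.73, camera adjusted p = 2.2e-06, adjusted p = 0.23 with an estimated correlation), with a median of 0.40 without YSGr female 10. Interferon gamma response genes had 1 of 24 risen (2 adjusted over the list alone, median 0.64, camera adjusted p = 4.1e-06, adjusted p = 0.15 with an estimated correlation). MHC class II genes had 3 of 9 risen (6 adjusted over the list alone, median 1.71, camera adjusted p = 1.2e-05, adjusted p = 0.15 with an estimated correlation). MHC class I genes had 0 of 12 risen (1 adjusted over the list alone, median 0.51, camera adjusted p = 0.018, adjusted p = 0.38 with an estimated correlation), a call that ended without YSGr female 10 (median 0.17, adjusted p = 0.20). Of the 22 lists past the threshold in females (11 higher, 11 lower), 1 passed with an estimated correlation and 14 kept the camera call in all 12 leave-outs. Oligodendrocyte markers were lower (median -0.64, camera adjusted p = 0.0050, adjusted p = 0.39 with an estimated correlation), a call that ended without YSGr female 12 (median -0.03, adjusted p = 0.24).

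The female count rested on several libraries: 166 without SG female 4, 96 without SG female 5, 94 without SG female 6 and 136 without YSGr female 10, but 785 without SG male 2, which is in the fit only through the shared spread, and 4483 with library weights. Of the 59 named genes called in females, 25 kept the call in all 12 leave-outs; Robo3, Grb10 and H2-Aa, among the leading genes, lost it in at least 1 (adjusted p up to 0.10, 0.065 and 0.075).

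In males 1111 genes passed the threshold, 627 higher and 484 lower (4228 at an unadjusted p under 0.05). Lcn2 rose by 6.24 (SE 0.67, adjusted p = 0.00047), C3 by 4.64 (SE 0.50, adjusted p = 0.00047) and Steap4, a metalloreductase gene, by 3.84 (SE 0.33, adjusted p = 0.00019). The other leading increases were Tgm1, Mndal, Cd74, Shisa3, Cxcl1, Snhg11 and Cbx7, at 3.28 to 4.87. Loxl1 fell by 2.94 (SE 0.26, adjusted p = 0.00019). Other leading decreases included Yap1, Pdlim3, Duxbl2, Tuba1c, Igf2bp1, Mymx, Eno1b and Gpr50, at -4.71 to -2.70, of which Duxbl2, Tuba1c and Eno1b have near-identical copies and are uncertain. Mmp9, a matrix metalloproteinase gene of neutrophils, rose by 3.32, Ifit1 by 2.60 and Thbs1, which encodes a matrix glycoprotein, by 2.51.

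Chemokines and cytokines had 10 of 20 risen in males (13 adjusted over the list alone, median 1.36) and macrophage markers 6 of 16 (6 adjusted over the list alone, median 0.62), and both calls held in the 2 camera tests (adjusted p = 2.3e-10 and 1.1e-05, and adjusted p = 0.029 and 0.042 with an estimated correlation). Complement genes rose in 9 of 16 cases (12 adjusted over the list alone, median 1.08) and neutrophil markers in 5 of 8 (7 adjusted over the list alone, median 3.02), each with adjusted p = 0.10 with an estimated correlation (camera adjusted p = 3.0e-09 and 1.6e-07). Type I interferon response genes rose in 7 of 25 cases (16 adjusted over the list alone, median 0.91), interferon gamma response genes in 7 of 24 (14 adjusted over the list alone, median 1.18), MHC class I genes in 2 of 12 (7 adjusted over the list alone, median 0.69) and MHC class II genes in 4 of 9 (5 adjusted over the list alone, median 1.95, but 1.24 without SG male 2). These 4 lists passed camera (adjusted p = 3.0e-09, 1.8e-08, 0.0011 and 0.00048) and not with an estimated correlation (adjusted p = 0.26, 0.16, 0.37 and 0.37). Ribosomal protein genes fell in 17 of 30 cases and rose in 0 (27 and 0 adjusted over the list alone, median -0.84), including Rplp0 at -1.16 and Rps3 at -0.85 (camera adjusted p = 2.0e-11, adjusted p = 0.37 with an estimated correlation). Their median was -0.52 without SG male 2 and -0.39 without libraries 2 and 8. Cell cycle genes fell in 4 of 30 cases (13 adjusted over the list alone, median -0.49), among them Mcm2, Mcm5 and Mcm7 of the replicative helicase (camera adjusted p = 2.0e-06, adjusted p = 0.46 with an estimated correlation). That median was -0.30 without YSGr male 8. Extracellular matrix genes rose in 4 and fell in 3 of 20 cases (4 and 4 adjusted over the list alone, median -0.03 with mean above 0, camera adjusted p = 0.79). Endothelial markers rose in 1 and fell in 2 of 14 (1 and 2 adjusted over the list alone, median -0.08, camera adjusted p = 0.80). Pericyte, fibroblast and meningeal markers rose in 1 and fell in 3 of 17 (1 and 3 adjusted over the list alone, median -0.13, camera adjusted p = 0.40). The pericyte list passed without YSGr male 8 (median -0.63, adjusted p = 0.022) and had a median of 0.30 without YSGr male 9 (adjusted p = 0.96). The endothelial median was -0.34 without YSGr male 8 (adjusted p = 0.12). Of 15 lists past the threshold (10 higher, 5 lower), 2 passed with an estimated correlation and 12 kept the camera call in all 12 leave-outs.

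The male count was 352 without SG male 2, 548 without SG male 3, 537, 506 and 512 without SG females 4, 5 and 6, 289 without YSGr male 8, 675 without YSGr male 9 and 2326 with library weights. Of the 101 named genes called in males, 43 kept the call in all 12 leave-outs, among them 13 of the 20 leading genes. The other 7 each lost it without SG male 2. Pdlim3 and Snhg11 lost it in 8 leave-outs (adjusted p up to 0.12 and 0.15), Mndal in 4 (0.069), Duxbl2 in 3 (0.092), Gpr50 in 2 (0.058), and Tuba1c and Eno1b in 1 (0.060 and 0.062).

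**Figure D3:**
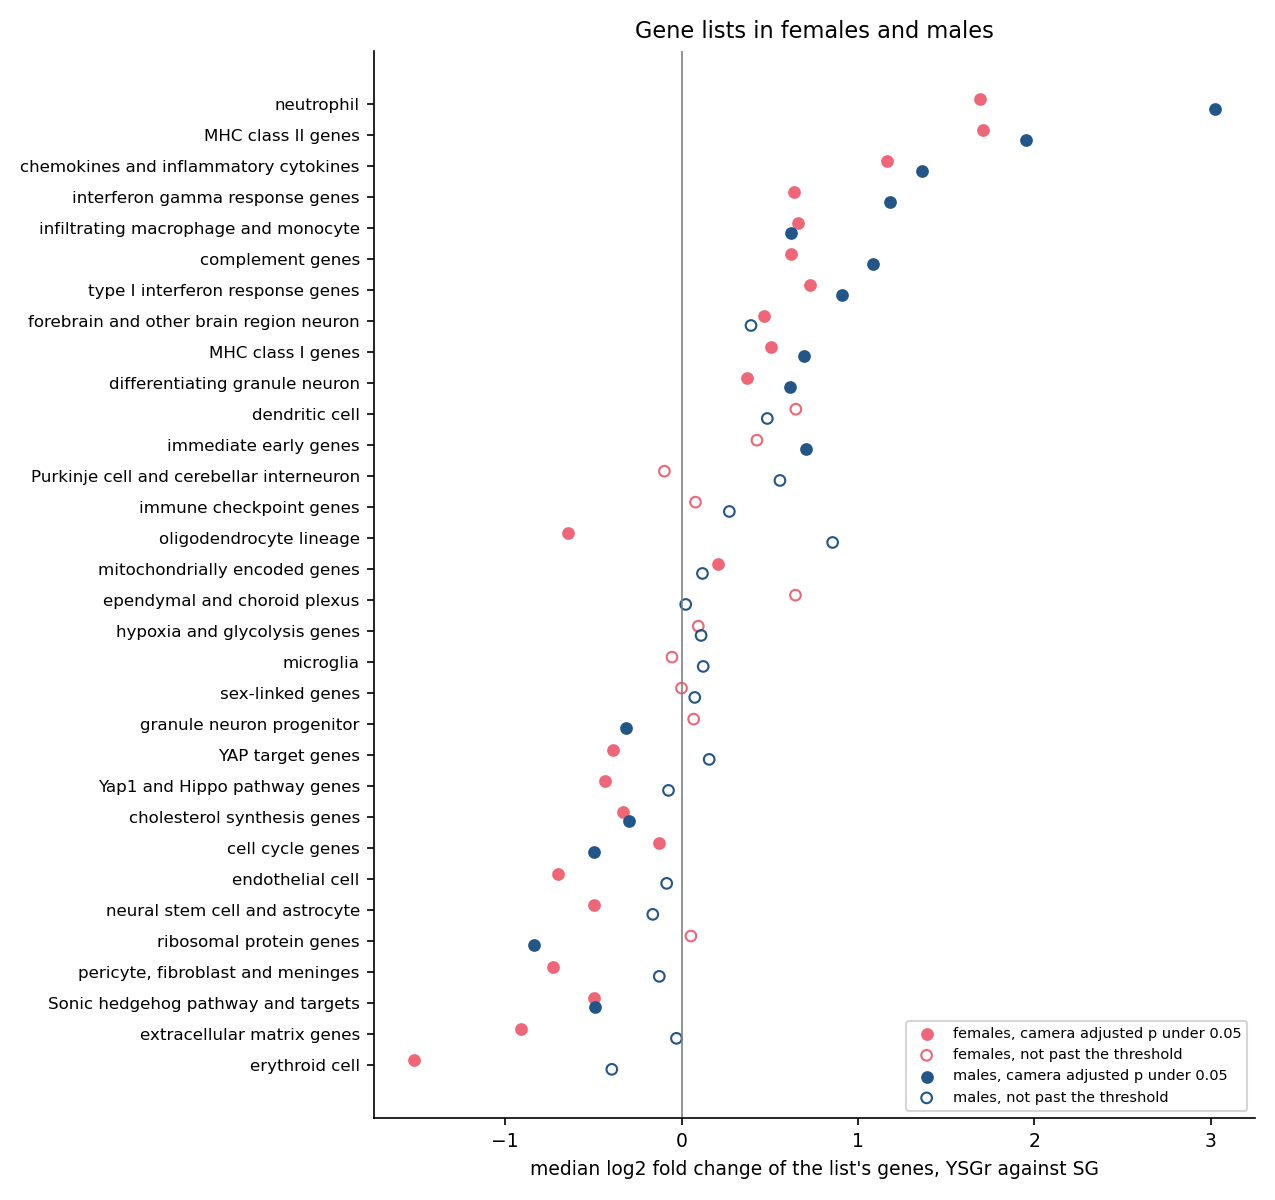
Median log2 fold change of YSGr against SG for the genes of each tested list, in females (red) and males (blue); filled points passed camera at an adjusted p under 0.05 and open points did not. Immune lists lie to the right in both sexes, while ribosomal protein genes lie at 0.05 in females and -0.84 in males.

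Female and male effects overlapped. Both tests used the same estimate of the spread of a gene, which makes joint calls more likely than in independent lists. The same 211 genes passed in both sexes, 94 higher and 117 lower, against 7.18 and 9.03 expected for independent lists, and 0 passed in opposite directions. Of the female calls 407 (95.5%) had the same sign in males, and across all genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.49.

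The series names sex differences as its subject, and the difference between the female and the male effect was tested directly. Hmga1b was the 1 gene of 14147 past the threshold, with a difference of -4.58 (female minus male effect, SE 0.29, adjusted p = 1.2e-05), and 1634 genes had an unadjusted p under 0.05. It had 63.4 ± 6.3 CPM (SD, n = 3) in YSGr males and 2.51 ± 0.41 in YSGr females, against 96.9 ± 33.2 in SG males and 92.4 to 96.9 in the SG females. Hmga1, the near-identical gene it copies, went the other way within YSGr, with 97.6 ± 2.0 CPM in males and 202 ± 18 in females. Because reads can be assigned to either copy, both values are uncertain.

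**Figure D4:**
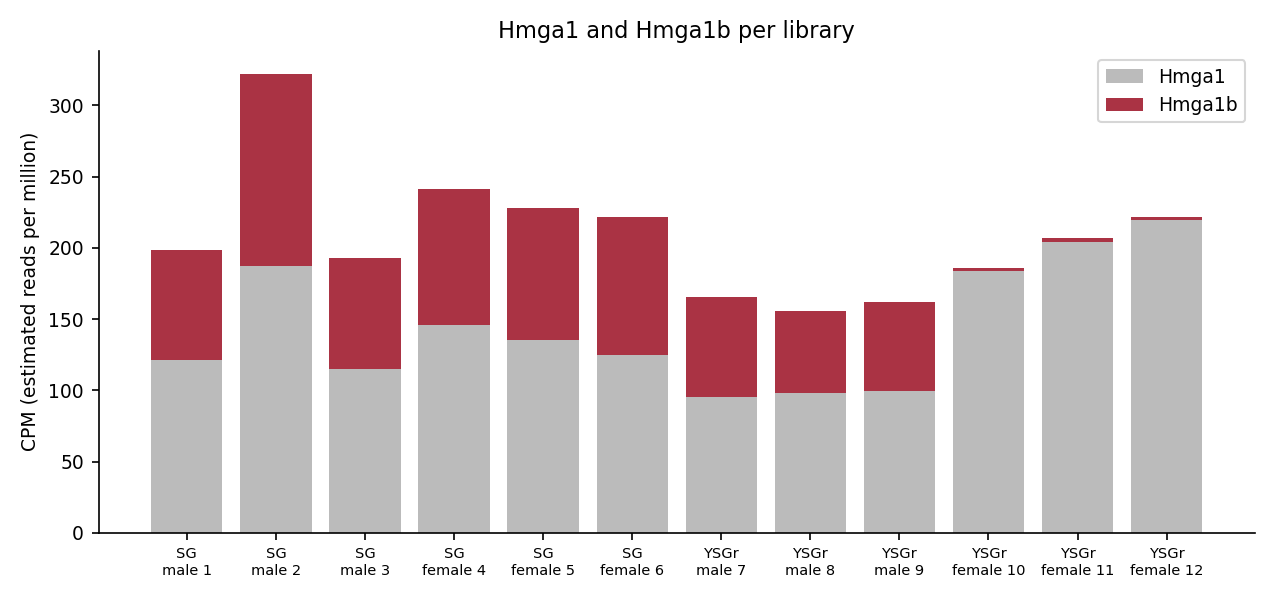
Stacked CPM of Hmga1 and Hmga1b in each of the 12 libraries, from estimated reads. Hmga1b makes up 36.9 to 43.7% of the sum in 9 libraries and 0.94 to 1.40% in the 3 YSGr females.

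Of 32 lists 13 differed between the sexes in their YSGr effect by camera, and 0 did with an estimated correlation or by fry. Ribosomal protein genes had 0 of 30 members past the threshold over all genes but 26 adjusted over the list alone, with a higher effect in females than in males (median difference 0.89, camera adjusted p = 4.6e-15, adjusted p = 0.43 with an estimated correlation). Without SG male 2 the median difference was 0.57, and with library weights 0.41. Extracellular matrix genes (median difference -0.65, camera adjusted p = 5.1e-06), pericyte markers (-0.60, adjusted p = 0.00066), endothelial markers (-0.41, adjusted p = 0.0015) and oligodendrocyte markers (-1.35, adjusted p = 0.0015) had a lower effect in females, each with adjusted p = 0.43 with an estimated correlation. The median difference was -1.02 for pericyte markers without YSGr male 9, -0.63 for endothelial markers without SG male 2, and -0.87 for oligodendrocyte markers without YSGr male 8 or without YSGr female 12. For endothelial markers the sexes lay farther apart in SG than in YSGr. Their mean log2 CPM was 3.26 in SG males and 3.64 in SG females, but 3.14 in YSGr males and 3.00 in YSGr females. Their lower effect in females thus came in large part from a higher level in SG females. The count of genes was 115 without YSGr female 11, 2 without YSGr male 7 or YSGr female 12, and 675 with library weights.

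Females and males were also compared within each genotype. In SG 5 genes passed, 1 higher and 4 lower in females, and 259 had an unadjusted p under 0.05, against 707 expected by chance. The 4 lower genes were Y-linked and checked the sex labels. Ddx3y had 0 estimated reads in the SG females and was at least 438-fold lower than in males (floor of 3 reads over the group), Eif2s3y at least 366-fold and Uty at least 227-fold, and Kdm5d had 1 read against 1115 (ratio 1112, 95% interval 199 to 43954). The higher gene was the predicted gene Gm26992, at 3.42 (adjusted p = 0.0029), which the rule for named genes leaves out and which was named after its value was seen. Of 7 lists past the threshold (0 with an estimated correlation), those of Hippo genes (median 0.23, camera adjusted p = 1.5e-05, adjusted p = 0.64 with an estimated correlation) and ribosomal proteins (median -0.26, camera adjusted p = 4.1e-06, adjusted p = 0.91 with an estimated correlation) both ended without SG male 2 (adjusted p = 0.20 and 0.24, medians 0.03 and 0.05). The ribosomal median was -0.43 without SG male 1 and -0.41 without SG male 3. The calls of YAP targets (median 0.30, camera adjusted p = 0.0047) and Hedgehog genes (median 0.17, adjusted p = 0.0014) also ended without SG male 2 (adjusted p = 0.19 and 0.054, medians 0.07 and 0.13). The extracellular matrix call (median 0.25, camera adjusted p = 0.0023) ended without SG female 6 (adjusted p = 0.096, median 0.15). The endothelial (median 0.30, camera adjusted p = 6.0e-06) and sex-linked calls held in all 12 leave-outs.

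In YSGr 11 genes passed, 3 higher and 8 lower in females, and 2566 had an unadjusted p under 0.05, against 707 expected by chance. All 12 libraries shared the estimate of the spread. A genotype whose libraries vary more than that estimate is tested too leniently, and one whose libraries vary less too strictly. The counts of 259 in SG and 2566 in YSGr therefore do not measure how far the sex difference differs between the genotypes. The same Y-linked genes were lower, each with 0 reads in females and bounds of at least 437-fold for Ddx3y, 379-fold for Kdm5d, 334-fold for Eif2s3y and 246-fold for Uty. Also lower in females were Hmga1b at -4.55 (SE 0.21, adjusted p = 4.3e-08) and Ctse, a cathepsin gene, at -2.36 (SE 0.28, adjusted p = 0.0024). So were Chil1, a secreted chitinase-like protein gene, at -1.81 (SE 0.23, adjusted p = 0.0048), and Mettl7a1 at -1.13 (SE 0.18, adjusted p = 0.047). Higher in females were Pagr1a at 2.87 (SE 0.33, adjusted p = 0.0020), which overlaps its near-identical copy Pagr1b, Hmga1 at 1.05 (SE 0.17, adjusted p = 0.044) and the predicted gene Gm26992 at 2.99 (adjusted p = 0.0068). Pagr1a was also higher in females within SG, at 3.26 to 4.20 log2 CPM against 1.97 to 2.24 in SG males, but did not pass there. Hmga1 lost the call in 9 of 12 leave-outs and Mettl7a1 in 10, with adjusted p up to 0.23 in each. Of 18 lists past camera (4 higher, 14 lower in females) 0 passed with an estimated correlation, and 12 kept the camera call in all 12 leave-outs. With all 12 libraries, oligodendrocyte markers had the largest median among them outside the sex-linked list, -1.66 (camera adjusted p = 6.1e-06, adjusted p = 0.31 with an estimated correlation). Of these markers 0 of 18 passed the threshold over all genes, and 12 were lower and 1 higher adjusted over the list alone. The median of Purkinje cell and interneuron markers was -1.24, but -1.99 without YSGr male 8 and -0.74 without YSGr female 10. The count of genes was 1029 without YSGr female 11, 24 without SG male 2, 7 when only the YSGr libraries were fitted, and 1819 with library weights.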

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

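The counts over other splits of the samples, the tests on the immune lists and the test of summed Hmga1 reads were chosen only after the results they bear on had been seen.

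A library lay far from the other 5 of its genotype in 10 of 104 sets of values, where chance gives about 1 in 20, or 5.2. SG male 2 accounted for 6 of them. Its mean log2 CPM over Hippo pathway genes was 4.72 (others 5.30 to 5.43), over YAP targets 3.64 (others 3.98 to 4.18), over Hedgehog genes 6.97 (others 7.30 to 7.49), over MHC class I genes 2.74 (others 2.47 to 2.57) and over ribosomal protein genes 9.86 (others 8.85 to 9.03), and Ptch1 was 8.30 (others 9.48 to 9.95). SG female 5 had 0.97 over interferon gamma response genes (others 1.28 to 1.41). YSGr female 12 had 2.83 over immediate early genes (others 3.49 to 3.85). SG male 3 had a Gli1 level of 8.14 (others 8.35 to 8.47), and SG male 1 a Gfap level of 8.66 (others 7.80 to 8.04).

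The YSGr effect differed between females and males for 1 gene and 13 lists by the test of the difference itself. Hmga1b had a difference of -4.58 (female minus male effect). Median differences were -0.49 for Hippo genes, -0.61 for YAP targets, 0.31 for cell cycle genes, -0.42 for type I interferon and -0.27 for interferon gamma response genes, -0.65 for extracellular matrix genes, 0.89 for ribosomal protein genes, 0.26 for granule neuron progenitor, -1.35 for oligodendrocyte, -0.98 for neutrophil, -0.41 for endothelial, -0.60 for pericyte and -0.77 for Purkinje cell and interneuron markers. Of these 13 lists 0 passed with an estimated correlation or by fry.

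Leaving out 1 library ended the call or moved the median of most of these lists. The type I interferon call ended without SG male 1 (adjusted p = 0.0503), SG male 3 (0.051), SG female 6 (0.063), YSGr male 7 (0.11), YSGr male 9 (0.053), YSGr female 11 (0.21) or YSGr female 12 (0.26, median -0.24), and its median was -0.25 without SG male 2 and -0.68 without YSGr female 10. The interferon gamma call ended without SG male 1 (adjusted p = 0.058), SG female 6 (0.067), YSGr male 7 (0.072), YSGr male 9 (0.053), YSGr female 11 (0.21, median -0.14) or YSGr female 12 (0.10), and its median was -0.43 without SG female 5 and -0.52 without YSGr female 10. The Purkinje cell and interneuron call ended without YSGr male 7 (adjusted p = 0.10, median -0.44), YSGr male 9 (0.050, just over the threshold), YSGr female 10 (0.080, median -0.44) or YSGr female 12 (0.11, median -0.42), and its median was -1.53 without YSGr male 8 and -1.64 without YSGr female 11. The neutrophil call ended without SG male 3 (adjusted p = 0.069), YSGr male 9 (0.050, just over the threshold) or YSGr female 12 (0.11). The progenitor call ended without SG male 3 (adjusted p = 0.069) or YSGr male 8 (0.072, median 0.15), and its median was 0.39 without YSGr male 9. The cell cycle call ended without YSGr female 12 (adjusted p = 0.10, median 0.15), and its median was 0.16 without YSGr male 8 and 0.59 without YSGr female 11. The other calls held in all 12 leave-outs, but medians moved to -0.19 for Hippo genes, 0.57 for ribosomal protein genes and -0.63 for endothelial markers without SG male 2, to -0.38 for YAP targets without YSGr female 12, to -0.87 for oligodendrocyte markers without YSGr male 8 or YSGr female 12, and to -1.02 for pericyte markers without YSGr male 9.

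The 8 immune lists of YSGr passed camera in both sexes, although in females MHC class I lost the call without YSGr female 10 (adjusted p = 0.20, median 0.17 against 0.51), the type I interferon median fell to 0.40 from 0.73 without it, and with an estimated correlation 1 of the lists passed in females and 2 in males. For the averaged comparison 3 technical explanations were weighed. Without YSGr male 8, the library farthest out in the principal components, 8 of 8 immune lists kept the camera call, which argues against 1 library with other cells in it. After correction for exon length and GC content 8 of 8 kept it, which argues against such a bias as the whole cause. If a lower share of tumour cells were the only change, markers of every other cell type would rise. The endothelial list had a median of -0.34 with 5 members that fell, against medians of 0.59 to 2.42 for the immune lists. This cannot exclude a lower share, since vessel genes may fall on their own. The Hedgehog and cell cycle lists were also lower in YSGr, which a lower share would give too. The endothelial call was lost without YSGr male 7 (adjusted p = 0.076), and in males alone the list had a median of -0.08 (-0.34 without YSGr male 8) and was not past the threshold. A change in immune cells or in gene activity that goes with the genotype stays open, as does a lower share of tumour cells. Any difference in collection between genotypes also stays open, since bulk tissue does not separate them.

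Hmga1b was nearly missing in the 3 YSGr females, while Hmga1 was higher there. If reads had only moved between the near-identical copies, the summed CPM would match between YSGr females and males, but the sums were 186 to 221 in females and 156 to 165 in males, with no overlap. Their means differed by a ratio of 1.27, below the 1.5 set for excluding shared reads, so this explanation stays open. A sequence variant or a loss of the Hmga1b copy in the animals that gave these 3 libraries was not tested. Hmga1b was at 92.4 to 96.9 CPM in the 3 SG females, which argues against sex alone. Shared parentage of the libraries of a group may account for it, and was not tested.

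Ribosomal protein genes were lower in YSGr males and not in YSGr females. The median difference of effects was 0.648 after correction for exon length and GC content (camera adjusted p = 4.8e-15), which argues against that bias as the whole cause. It was 0.570 at the lowest over 12 leave-outs, without SG male 2, and 1.05 at the highest, so no single library made up the whole difference, but that library moved it by over 1.5 times. It was 0.452 without libraries 2 and 8 and 0.410 with library weights, and the list had adjusted p = 0.43 with an estimated correlation and 0.23 by fry. A difference between males and females may underlie it, but RNA quality was not measured in the data used here and stays open.

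Other splits of the same libraries were counted for each number of genes called. For the averaged comparison 1 of 100 splits, the real one, gave as many genes (1617, highest other 7). That is the lowest share that 100 splits can give. Splits that mix the genotypes count the difference between them as spread, which lowers their counts. The share argues against chance only if the libraries are independent samples, which the labels do not state. For the difference between the sexes 10 of 100 splits gave as many as the real 1 (highest other 3). These splits moved genotype labels within each sex, and uneven ones took part of the genotype difference into the difference between the sexes. A count of genes also ignores the size of a change. For this comparison the splits therefore cannot decide for or against chance. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real counts and the highest others were 426 and 0 in females, 1111 and 0 in males, and 5 and 0 between the sexes of SG, each with 1 of 10 splits as large. Between the sexes of YSGr 2 of 10 splits gave at least the real 11, and the highest other gave 64, which points to a structure of the samples other than sex, since it set YSGr male 8 with YSGr females 10 and 12 against the other YSGr libraries.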

How the results depend on the processing

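The voom fit, the length and GC correction and the fit without libraries 2 and 8 were chosen after the data were seen, and all other alternatives before. No paired analysis was possible because the library numbers are not shared between groups. Under the filters, pseudocounts, scalings, variance models and voom, counts of genes stayed within 1.5 times in all 6 comparisons. Library weights, which put SG male 2 at 0.10 and YSGr female 11 and YSGr male 8 at 0.27 and 0.28, gave 4986 genes averaged over the sexes, 4483 in females, 2326 in males, 675 for the difference between the sexes, 28 between the sexes of SG and 1819 between those of YSGr. The length and GC correction gave 678 in females, 1744 in males, 23 between the sexes of YSGr and 20 lists for the difference between the sexes. Without libraries 2 and 8 there were 1267 in females, 247 in males and 19 between the sexes of YSGr. Fitting only the groups compared gave 761 in females, 318 in males (76.4% of them higher in YSGr, against 56.4%) and 7 between the sexes of YSGr. Lists past the threshold with an estimated correlation were 2 averaged, 1 in females, 2 in males and 0 in each of the other comparisons, and by fry 12 in females, 0 for the difference between the sexes, and 1 between the sexes of each genotype. The cause was not tested, other than that fits with fewer libraries estimate the spread from fewer values.

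Leaving out 1 library gave 903 to 2087 genes averaged over the sexes, 94 to 785 in females, 289 to 1665 in males, 1 to 115 for the difference between the sexes, 5 to 5 between the sexes of SG and 9 to 1029 between those of YSGr. Lists past the threshold were 18 to 22, 18 to 23, 13 to 19, 8 to 19, 6 to 8 and 17 to 21 in the same order. The lowest counts came without SG female 6 (903 and 94), YSGr male 8 (289) and YSGr female 12 (8 lists), and the highest without YSGr female 12 (2087), SG male 2 (785) and YSGr female 11 (1665, 115 and 1029). Of 12339 values of named genes under the alternatives 11063 kept direction and side of the threshold, 842 lost the call and 268 gained one. Another 166 moved, which means a change of direction with no call in either fit. A change of direction with a call in either fit counts as reversed, and 0 did so. Of 5178 list values 4589 kept both, 274 lost the call, 151 gained one, 157 moved and 7 reversed. The ribosomal list between the sexes of SG reversed to a mean of 0.043 with library weights and 0.045 without SG male 2 or without libraries 2 and 8 (-0.44 to 0.04 over the leave-outs). The cell cycle list in females reversed to 0.082 without YSGr female 11 (-0.32 to 0.08 over the leave-outs). After the length and GC correction the mitochondrially encoded list reversed to -0.067 in females, -0.470 for the difference between the sexes and 0.232 between the sexes of SG. The cause was not tested. At 0.100 to 0.111 CPM per read, the T cell genes Cd3e and Cd8a were too low to test.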

Other observations

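The tests of a neighbouring-gene pattern and of DNA next to Yap1 were specified before their results were seen, but the gene patterns that prompted them had been seen. The astrocyte test without genes of other lists was chosen after the result for the whole astrocyte list had been seen.

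Among genes past the threshold with an absolute log2 fold change above 1, 14 runs of at least 4 lay with less than 500 kb between neighbours. In 5 of them all genes were higher in YSGr, in 1 all were lower (Lsp1, Prr33, Igf2 and Gm49394 on chromosome 7) and 8 held genes of both directions, such as Csf2rb2 to Lgals1 on chromosome 15 with 2 higher and 4 lower. Of the runs with all genes higher, H2-Ab1, H2-Aa, H2-Eb1, C4b, Cfb, Hspa1b and Hspa1a made up 7 genes on chromosome 17. On chromosome 1 the Fc receptor genes Fcgr2b, Fcgr4, Fcgr3 and Fcer1g with Pcp4l1, Ly9 and Cd48 (170958617 to 171705258) made a run of 7 higher genes, and the interferon-inducible genes Aim2, Ifi207, Ifi204, Mndal and Ifi203 (173350879 to 173942672) a run of 5. On chromosome 11 the chemokine genes Ccl2, Ccl7, Ccl11 and Ccl8 (82035571 to 82116799) made a run of 4, and Slfn8, Slfn2, Slfn4, Ccl9, Ccl6 and Wfdc17 (83002158 to 83706268) a run of 6. Of the mixed runs, the one that holds Yap1 on chromosome 9 had the metalloproteinase genes Mmp12, Mmp3 and Mmp8 higher. Fc receptors bind antibodies on myeloid cells, and Slfn genes are interferon-inducible. The runs named were picked after their values were seen.

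A strain variant carried with the floxed allele could raise or lower neighbouring genes together. Of 561 genes past the threshold with an absolute log2 fold change above 1, 147 had a neighbour within 500 kb that changed the same way and had another name stem. Random sets matched on level had a median of 122.5, a 95th percentile of 147.2 and a highest value of 158, and 6 of 100 were as large. The bound written for excluding the hypothesis was met by less than the spread of the random sets, and the rule that leaves such a case open was set after the value was seen. Within 10 Mb of Yap1, 7 of 46 genes (15.2%) had changed, against 1606 of 14015 elsewhere (11.5%), a two-sided Fisher's exact p of 0.36 and an odds ratio of 1.39 (95% interval 0.52 to 3.14). This interval allows both no excess and a 3.14-fold one, so flanking DNA stays open as well.

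The rise of genes such as Lcn2 and Gfap prompted the hypothesis that astrocytes in YSGr tissue are in a reactive state. A list of reactive astrocyte genes was tested in the averaged comparison, without 5 genes that had prompted it (Lcn2, Steap4, Cp, Cxcl10 and Tgm1) and without 9 members of other lists whose values had been seen, Gfap and Timp1 among them. Of the remaining 21, 11 rose and 1, Emp1 at -0.71, fell (median 0.67, camera p = 4.7e-06, and p = 0.040 with an estimated correlation). Higher members included Ptgs2 at 2.36, Ptx3 at 2.22, Cd14 at 1.88, Srgn at 1.80 and Serpina3n at 1.67. With the 9 members kept, 17 of 30 rose (median 0.73, camera p = 9.3e-09, and p = 0.028 with an estimated correlation), a result that was fixed in part by values already seen. In the list with those members, the part described for neuroinflammation had camera p = 0.014 with an estimated correlation and the part described for ischaemia p = 0.011. The part common to both had 4 of 9 risen and 0 fallen, with camera p = 0.0026 at the preset correlation but p = 0.19 with an estimated one. The list of neural stem cell and astrocyte markers was lower in the same comparison, with 6 of 20 fallen and Gfap alone risen. The test of 21 genes goes with the hypothesis, but these genes are a part of the list whose result had been seen. The p-values of this list and its parts were not adjusted for the number of parts tested. The part common to both passed only at the preset correlation. Cd14, Srgn and Ptgs2 are also expressed by myeloid cells, which may account for them in bulk tissue.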
